A study of Mus musculus with 11 samples.

How the data were processed

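RNA sequencing libraries were made from mouse bone marrow derived macrophages in an M0 or an M1 state. The cells had received a gapmer against the long noncoding RNA MERRICAL (KD) or a gapmer labelled NS (NS) for 16 hours. A gapmer is a short antisense oligonucleotide that directs cleavage of the RNA it pairs with. The 11 libraries formed 4 groups, with 3 libraries of M0 NS, 3 of M0 KD, 3 of M1 NS and 2 of M1 KD. The labels number the libraries 1, 2 and 4 in the first 3 of these groups, and 5 and 6 in M1 KD. What the numbers stand for, the stimulus behind the M1 label and the strand setting of the counting are not given in the sources used here. Nothing states that replicates are separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

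Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used with the mouse genome build GRCm38. The deposited count table holds a raw count per gene and library for 42375 named genes. Its values are whole numbers, and 1 further entry with a blank name was left out. The second deposited table holds a normalized signal for 22812 genes. Checked against the counts, that signal was the raw count divided by 1 constant per library, which equalled the median-of-ratios size factor, for genes with a total of at least 6 counts. Total counts per library ran from 30040632 to 43250392. How reads shared by paralogs or pseudogenes were counted is not given in the sources used here, which limits values of ribosomal protein genes and of gene families such as the guanylate-binding proteins and class I antigens.

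Differential expression was tested on the raw counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups, a minimum count of 10 and a minimum total of 15, which left 15024 genes. Libraries were scaled by TMM factors. All 11 libraries entered a single quasi-likelihood fit with a coefficient per group (glmQLFit with the robust option, glmQLFTest), since 1 group had 2 libraries. The 4 comparisons were M1 NS against M0 NS, M0 KD against M0 NS, M1 KD against M1 NS, and the difference between the latter effects. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and each standard error is that of the log2 fold change. Group levels are given as CPM, the count scaled to a common library total with TMM factors, mean ± SD.

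Gene groups were 32 lists with 871 members, of which 867 matched a gene name and 5 of these by an older symbol. The lists covered macrophage activation, chemokines, metabolism, the cell cycle, stress responses, other cell types and RNA quality. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Their p-values were adjusted over the 32 lists of a comparison. Camera compares a list with all other genes, whereas fry asks whether its members move one way on balance. Members called are counted over all genes tested and also adjusted over the list alone. Known from the study, the chemokine genes Ccl3 and Ccl4 were reported in every comparison whatever their p.

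The groups, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. The rule took the 5 called genes with the largest rise and the 5 with the largest fall among those with a mean log2 CPM of at least 3, an established symbol and CPM ranges of the compared groups that did not overlap (no such demand for the difference of effects). It added the 2 called members with the smallest p from each of the 10 lists with the smallest camera p (6 lists for M1 NS against M0 NS). Where no gene was called it took the 3 of each direction with the smallest p. List members named to explain a count of 5 or fewer were chosen after their values were seen. Gene positions, lengths, GC contents and exon numbers came from GENCODE M21 on GRCm38, which may not be the annotation the authors used.

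Alternatives were DESeq2 1.42.0 with its Wald test, limma-voom, limma-trend on log2 of the authors' normalized values plus 1, edgeR with other scaling factors, other filters on low counts, the robust option off, stricter thresholds, fits of the 2 compared groups alone, the label number as a block over 9 libraries, and each library left out in turn. Chosen after seeing the data were the removal of a smooth trend in transcript length, GC content and exon number from each library, and the repeated fits of the 6 M0 libraries alone. The procedure was tested on simulated data with 100 genes changed at each fold. There, each gene had the same baseline and the same spread in all groups, and all other genes were unchanged. The data differ in these respects, so the shares hold for these settings only. At a 2-fold change it recovered 53% of them in M0, 41% in M1, 17% for the difference of effects, 47% for M1 NS against M0 NS and 68% with the 6 M0 libraries alone. At a 4-fold change these shares were 76%, 79%, 65%, 83% and 92%. All recovered genes had the right sign, and false calls numbered 9, 9, 10, 8 and 6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.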

Results

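RNA levels were measured in bone marrow derived macrophages in the M0 or M1 state after 16 hours with a gapmer against MERRICAL or with the NS gapmer. Total counts were 38405896, 34182604 and 36298045 in M0 NS replicates 1, 2 and 4, and 33472828, 36105543 and 40444283 in M0 KD replicates 1, 2 and 4. They were 42724382, 30040632 and 38659909 in M1 NS replicates 1, 2 and 4, and 43250392 and 33140909 in M1 KD replicates 5 and 6. The first principal component of log2 CPM held 70.1% of the variance and parted M0 from M1 libraries. The second held 12.5% and parted M1 NS, at 39.3 to 54.1, from M1 KD, at -75.2 and -62.7. No gene in the table carries the name MERRICAL, so the level of the target was not analysed here.

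**Figure D1:**
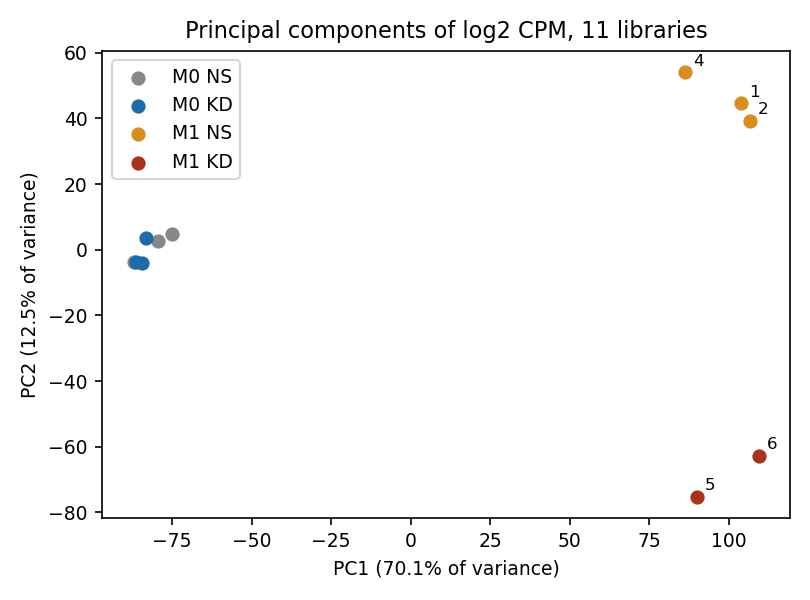
Principal component scores of the 11 libraries, a point per library, coloured by group, with label numbers at the M1 points. On the second axis the M1 NS libraries sit between 39.3 and 54.1 and the M1 KD libraries at -75.2 and -62.7, while the 6 M0 libraries lie between -4.10 and 4.90.

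M1 cells with the NS gapmer were compared with M0 cells with the same gapmer to see how far the states differ. Il12b, a subunit of interleukin 12, rose from 0.795 ± 0.0972 to 682 ± 215 CPM (SD, n = 3 each; log2 fold change 9.74, SE 0.42, adjusted p = 6.11e-09). Nos2, the inducible nitric oxide synthase, rose from 5.54 ± 1.49 to 3975 ± 194 CPM (log2 fold change 9.48, SE 0.29, adjusted p = 6.26e-10). Ptgs2, the inducible cyclooxygenase, the cytokine gene Il6 and the uridine phosphorylase gene Upp1 also rose, by log2 fold changes of 9.51, 9.23 and 9.06. Cd163, a scavenger receptor for haemoglobin, fell from 47.2 ± 7.38 to 0.349 ± 0.170 CPM (log2 fold change -7.02, SE 0.40, adjusted p = 4.84e-08). The transporter gene Slco2b1, the lectin gene Clec10a, the scavenger receptor gene Stab2 and Zfyve28 fell as well, with log2 fold changes of -7.56, -7.19, -7.06 and -7.17. Ccl3 and Ccl4, neighbouring chemokine genes, rose by 2.85 (SE 0.30, adjusted p = 6.96e-06) and 3.04 (SE 0.42, adjusted p = 5.79e-05) on the log2 scale.

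The inflammatory gene groups rose together with M1. All 43 tested genes of the interferon gamma response and antigen presentation rose, with Gbp4, a guanylate-binding protein, at 8.02 and Cd274, which encodes PD-L1, at 5.23. Of 57 type I interferon response genes 54 rose, among them Oasl1 at 6.17 and Usp18 at 4.40. Of 27 classical activation markers 26 rose, as did all 30 NF-kappaB target and feedback genes, such as the signalling genes Ripk2 at 3.35 and Malt1 at 4.10, and all 19 inflammatory cytokines, such as Il1a at 6.32. Of 46 cell cycle and DNA replication genes 37 fell, among them Cenpf at -4.77 and the cyclin gene Ccna2 at -4.26. Adjusted over the list alone, the counts of these 6 groups were the same, 43, 54, 26, 30 and 19 higher, and for the cell cycle 37 lower. Camera gave adjusted p-values from 1.03e-19 for the interferon gamma list to 1.76e-09 for the cell cycle list. These calls were lost with the other setting, at adjusted p = 0.112 to 0.416 with an estimated correlation. That setting kept no list call in any of the 4 comparisons, so a loss with it does not part one list from another.

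Further groups passed camera between M1 NS and M0 NS, none of them with the other setting (adjusted p = 0.112 to 0.452 with an estimated correlation). Glycolysis and hypoxia genes were higher as a group (25 of 29 rose, median log2 fold change 1.63), as were antioxidant genes of the NRF2 response (18 of 25 rose, Mt1 and Ftl1 fell, median 1.22) and stress and unfolded protein response genes (19 of 34 rose, Vldlr and Shmt2 fell, median 1.01). Chemokine ligands were also higher, with 17 of 25 up and 7 down. Lysosome and endosome genes were lower (20 of 34 fell, median -0.69), as were cholesterol biosynthesis genes (15 of 24 fell, median -0.77). Neutrophil and granulocyte precursor markers were lower by a median of -3.62, with 14 of 16 down. LXR targets (14 of 20 fell; Nr1h3, Npc2, Nr1h2 and Mertk rose), lipid uptake and foam cell genes (14 of 21 fell; Acsl1, Hilpda, Cxcl16, Olr1 and Msr1 rose) and macrophage core genes (13 of 24 fell; Cd14, Fcer1g, Emr1, Mertk and Spi1 rose) had medians of -1.09, -1.24 and -0.89. Of 52 oxidative phosphorylation genes 28 rose, with a median of 0.38 that turned to -0.01 when libraries were scaled by their size only. With that scaling the stress gene median was 0.62 and the lysosome median -1.08. Adjusted over the list alone, the counts higher and lower were 25 and 0 for glycolysis, 18 and 2 for NRF2, 20 and 3 for stress genes, 17 and 8 for chemokine ligands, 0 and 14 for neutrophil markers, 4 and 14 for LXR targets, 5 and 14 for lipid uptake, 5 and 13 for macrophage core genes, and 28 and 0 for oxidative phosphorylation. Adjusted over the list alone, 21 lysosome genes and 16 cholesterol genes were lower. Camera adjusted p-values ran from 3.29e-09 to 0.0494. The other 15 lists did not pass camera, the lowest adjusted p being 0.0901. The call ended for lipid uptake without M0 NS replicate 4 (adjusted p = 0.0652) and without M1 NS replicate 1 (0.0606), and for macrophage core genes without M0 NS replicate 2 (0.0714), M1 NS replicate 1 (0.0573) or M1 NS replicate 4 (0.0996), or with the 6 NS libraries alone (0.0570). Removing the trend in length, GC content and exon number ended it for LXR targets (0.0622) and lipid uptake (0.0564), and the replicate block for LXR targets and macrophage core genes (0.0668 each). Where these calls ended the medians stayed near their size, at -1.11 and -1.04 for LXR targets, -1.30 to -1.13 for lipid uptake and -0.92 to -0.72 for macrophage core genes.

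Across all genes, 8338 of 15024 tested were called between M1 NS and M0 NS with edgeR, 4044 higher and 4294 lower. CPM ranges of the groups did not overlap for 61.4% of genes, where chance gives 10%. With library size as the only scaling, 8795 genes were called, 2348 higher and 6447 lower, so that 26.7% rather than 48.5% were higher, and the median log2 fold change of all genes was -0.42. It was -0.16 with upper-quartile factors.

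The effect of the MERRICAL gapmer in M0 cells was read from M0 KD against M0 NS. No gene passed the test over all 11 libraries, yet cell cycle and neutrophil genes differed as groups. Of 46 cell cycle and DNA replication genes 45 had a log2 fold change above 0 (median 0.58), and 21 passed higher when adjusted over the list alone. Their camera adjusted p was 6.98e-18, but adjusted p = 0.529 with an estimated correlation and 0.124 with fry. All 16 neutrophil and granulocyte precursor markers were below 0 (median -1.21), and 14 passed lower when adjusted over the list alone. Camera gave them an adjusted p of 3.77e-11, against adjusted p = 0.149 with an estimated correlation and 0.0271 with fry. Among these markers, the granule protein gene Ngp was at 460 ± 131 CPM in M0 NS and 191 ± 10.1 in M0 KD, and Lcn2, which encodes lipocalin 2, at 119 ± 38.1 and 49.3 ± 1.38 (SD, n = 3 each). Ccl3 was at 26.2 ± 0.870 CPM in M0 NS and 33.8 ± 6.53 in M0 KD (log2 fold change 0.37, SE 0.28, adjusted p = 0.565). Ccl4 was at 12.7 ± 0.607 and 16.7 ± 2.30 CPM (log2 fold change 0.39, SE 0.39, adjusted p = 0.658).

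Smaller shifts of other groups also passed camera in M0. Mitochondrially encoded transcripts had a median log2 fold change of 0.47 (adjusted p = 0.00557), lost at adjusted p = 0.944 with an estimated correlation, and they made up 1.28 to 1.45% of counts in M0 KD against 1.02 to 1.14% in M0 NS. With the trend in transcript length, GC content and exon number removed, that median was 0.07 and the call ended (adjusted p = 0.477). Lower medians were found for oxidative phosphorylation genes (-0.24, adjusted p = 1.39e-06), NF-kappaB target and feedback genes (-0.36, 8.07e-05), ribosomal protein genes (-0.21, 9.08e-05), macrophage core genes (-0.28, 2.30e-04), interferon gamma response genes (-0.23, 0.00621), NRF2 response genes (-0.19, 0.0197) and adhesion and migration genes (-0.18, 0.0214). These calls were lost too, at adjusted p = 0.149 for the macrophage core genes and 0.803 to 0.944 with an estimated correlation for the others. Over the alternatives the medians ran from -0.28 to -0.16 for oxidative phosphorylation and from -0.30 to -0.16 for macrophage core genes, lowest in size with the trend removed, and from -0.41 to -0.02 for interferon gamma, -0.30 to -0.07 for ribosomal and -0.26 to -0.10 for adhesion genes. None of these 8 groups had a member called over all genes in the fit of the 11 libraries. Adjusted over the list alone, 4 NF-kappaB genes (Zc3h12a, Bcl3, Tnfaip2 and Nfkbiz) and 2 adhesion genes (Vasp and Mmp14) passed, all lower, and none in the other 6 groups. With fry, the macrophage core genes passed (0.0271) and the others did not. Left out in turn, single libraries ended the calls for ribosomal protein genes (median -0.07; M0 NS replicate 4, adjusted p = 0.130), interferon gamma genes (medians -0.02 and -0.11; M0 NS replicate 2, 0.743; M0 KD replicate 2, 0.151), NRF2 genes (M0 NS replicate 1, 0.135; M0 KD replicate 4, 0.555; the 6 M0 libraries alone, 0.0721; the trend removed, 0.119) and adhesion genes (median -0.15; M0 KD replicate 1, 0.0862). The NRF2 medians were then -0.14, -0.07, -0.18 and -0.12. The other 22 lists did not pass camera, the lowest adjusted p being 0.109.

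Over single genes, edgeR called 0 of 15024 in M0 KD against M0 NS, with 1947 genes at an unadjusted p under 0.05 where chance would give 751. The lowest adjusted p was 0.190, shared by the kinetochore gene Spc25 (log2 fold change 1.08), the kinase gene Cdk14 (0.83), the condensin gene Smc2 (0.81), Chil1 (-1.46), Lcn2 (-1.27) and the leukotriene receptor gene Ltb4r1 (-1.20). CPM ranges of the groups did not overlap for 35.1% of genes, where chance gives 10%. The count was 181 with the DESeq2 Wald test, 385 with no filter on low counts, and 0 with limma-voom and with limma-trend.

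The fit of the 6 M0 libraries alone, whose genes were looked at only after the larger fit had called none, gave 1103 called genes, 545 higher and 558 lower. In it Rgs1, a regulator of G protein signalling, rose from 41.4 ± 10.2 to 111 ± 23.9 CPM (SD, n = 3 each; log2 fold change 1.42, SE 0.21, adjusted p = 0.0235). The cyclin gene Ccne2 rose by 1.35 (SE 0.15, adjusted p = 0.0121), and so did Flrt2 by 1.35, Hmmr by 1.32, the kinetochore gene Casc5 by 1.21 and the spindle motor gene Kif11 by 1.001. Chil1, Itgb2l, the peptidoglycan recognition gene Pglyrp1, Lcn2 and Ngp fell, with log2 fold changes from -1.46 to -1.26. Of the cell cycle list 20 of 46 genes rose and none fell, and of the neutrophil list 9 of 16 fell and none rose. Adjusted over the list alone, 28 cell cycle genes were higher and 14 neutrophil markers lower. Lower too were the complement genes C1qc (-0.62) and C1qb (-0.58), the NF-kappaB feedback genes Zc3h12a (-0.64) and Nfkbia (-0.52), the actin regulator Vasp (-0.76), and Tfeb (-0.51), a transcription factor of lysosomal genes. Of 11 mitochondrially encoded transcripts 5 were called higher and none lower in this fit (median 0.48; 5 higher adjusted over the list alone), namely mt-Nd2 (0.48), mt-Nd4l (2.34, at under 1 CPM), mt-Nd4 (0.49), mt-Nd5 (0.44) and mt-Nd6 (0.43), chosen after values were seen. Camera gave them an adjusted p of 1.22e-05, against adjusted p = 0.655 with an estimated correlation and 0.0352 with fry. Whether RNA quality differed between the groups was not tested. Without M0 NS replicate 1 or 2, or M0 KD replicate 1 or 2, this fit called 0 genes; without M0 NS replicate 4 it called 1726 and without M0 KD replicate 4 it called 403. With the trend in length, GC content and exon number removed it called 18. Ccl3 and Ccl4 were not called by edgeR in the 6 M0 libraries alone. Their log2 fold changes there were 0.38 (SE 0.13, adjusted p = 0.102) and 0.40 (SE 0.11, adjusted p = 0.0605). The standard errors in the fit of the 11 libraries were larger, at 0.28 and 0.39.

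The effect of the MERRICAL gapmer in M1 cells was read from M1 KD against M1 NS. Ccl3 fell from 188 ± 48.2 CPM in M1 NS (SD, n = 3) to 39.8 ± 24.6 in M1 KD (SD, n = 2), a log2 fold change of -2.24 (SE 0.34, adjusted p = 4.45e-04). Ccl4 fell from 104 ± 43.03 to 15.8 ± 12.9 CPM, a log2 fold change of -2.72 (SE 0.48, adjusted p = 0.00116). In both M1 KD libraries, Ccl3 (at most 57.2 CPM) and Ccl4 (at most 24.9) lay below the lowest M1 NS library (156 and 56.1). Ranges that did not overlap were found for 52.4% of all genes tested, where chance gives 20%, so this is not particular to Ccl3 and Ccl4. Both genes have 3 exons and lie on chromosome 11 of GRCm38, Ccl3 from 83647844 to 83649355 on the minus strand and Ccl4 from 83662584 to 83664683 on the plus strand. Fpr1, the receptor for formyl peptides, fell from 168 ± 74.95 to 3.84 ± 2.02 CPM (log2 fold change -5.47, SE 0.43, adjusted p = 6.78e-06). Egr1, an immediate early transcription factor, fell by 5.14 on the log2 scale, the scavenger receptor gene Marco by 3.40, the RNA-binding protein gene Rbm12 by 3.71 and Spata13 by 3.24. Spata13 varied widely in M1 NS, at 70.5 ± 57.7 CPM (SD, n = 3, from 37.1 to 137). Its log2 fold change ran from -3.55 to -2.28 over the alternatives. Among genes at a mean log2 CPM of at least 3 over all 11 libraries, the rule for named genes took 5 rises. They were Aph1c, a subunit of gamma-secretase (3.46, SE 0.23, adjusted p = 4.26e-06), Mgll, the monoacylglycerol lipase (3.41), Frat2 (3.40), Atp6v0d2, a subunit of the vacuolar proton pump (3.36), and Pcp4l1 (3.33). In M1 NS these were at 4.33, 2.94, 0.43, 12.4 and 0.63 CPM, so most of these rises started from low levels.

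**Figure D2:**
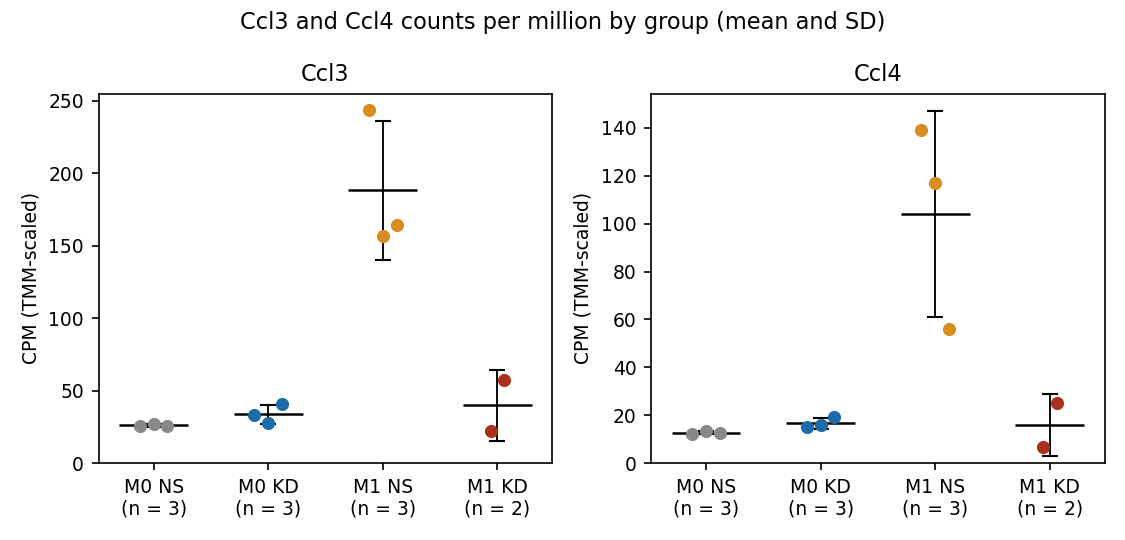
CPM of Ccl3 and Ccl4 in each of the 11 libraries by group, with points for libraries and the mean ± SD of the group. Ccl3 has a mean of 188 in M1 NS and 39.8 in M1 KD, and Ccl4 104 and 15.8.

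Ribosomal and lysosomal genes rose in M1 KD. Of 46 cytosolic ribosomal protein genes 33 rose and none fell (median log2 fold change 0.67; 40 higher adjusted over the list alone), among them Rps24 at 0.99 and Rps7 at 1.10. Of 34 lysosome and endosome genes 22 rose (median 0.70; 22 higher and 1 lower adjusted over the list alone), such as Cd68, from 362 ± 61.5 to 1788 ± 327 CPM, while the scavenger receptor gene Stab1 fell (-1.79). Of 21 lipid uptake and foam cell genes 11 rose (median 0.77; 12 higher and 3 lower adjusted over the list alone), among them the galectin gene Lgals3 at 2.37 and the fatty acid binding protein gene Fabp5 at 2.94. Lrp1 (-1.95), Acsl1 (-1.25) and Apobr (-1.18) of that list fell. Of 46 cell cycle and DNA replication genes 19 rose, with a list median of 0.48. Adjusted over the list alone, 21 were higher and 2 lower. Among the rises were the mitotic kinase gene Plk1 at 2.61, from only 0.34 CPM in M1 NS, and the replication helicase gene Mcm7 at 1.40. Tk1 (-1.55) and Hells (-0.82, with -0.90 to -0.51 over the alternatives) were called lower. Camera gave these 4 groups adjusted p-values of 5.54e-09, 7.64e-06, 0.0258 and 0.0183, all lost at adjusted p = 0.871 to 0.879 with an estimated correlation. With fry, the cell cycle genes did not pass (adjusted p = 0.153) and the others did (0.0224, 0.00166 and 0.00212). The lysosome median ran from 0.44, with the trend in length, GC content and exon number removed, to 0.83 without M1 KD replicate 6. The cell cycle call ended without M1 NS replicate 4 (adjusted p = 0.125) or M1 KD replicate 6 (0.0655), with a median of 0.46 in each case.

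Genes for sensing and migration were lower in M1 KD. Of 28 Toll-like receptor and nucleic acid sensing genes 14 fell, among them Tlr8, a receptor for single-stranded RNA, at -2.19 and Irak3, an inhibitor of Toll-like receptor signalling, at -1.77, and Tmem173 was called higher (0.48, with 0.24 to 0.64 over the alternatives; the same counts adjusted over the list alone). Of 20 chemokine receptor genes 9 fell, among them Fpr1 and the complement receptor gene C5ar1 (-2.49), while Cxcr4 (2.11) and Ccrl2 (1.86) rose (9 lower and 3 higher adjusted over the list alone). Of 31 adhesion and migration genes 12 fell, among them the actin regulators Coro1a (-2.16) and Dock8 (-1.78), while Mmp12 (3.23) rose and Itgb7 (1.64) was called higher (14 lower and 3 higher adjusted over the list alone). Without M1 KD replicate 5 the log2 fold change of Itgb7 was 0.06 (adjusted p = 0.891), and it lost the call in 7 of 16 alternatives. Of 15 genes of the WDR5 and MLL histone methyltransferase complex 7 fell and none rose (7 lower adjusted over the list alone), such as Hcfc1 (-1.49) and Kmt2b (-1.10). Medians of these groups were -0.49, -0.78, -0.46 and -0.29, with camera adjusted p-values of 0.0183, 0.0435, 0.0187 and 0.0183, all lost at adjusted p = 0.871 to 0.879 with an estimated correlation. With fry all of them passed (0.0108, 0.00166, 0.00386 and 0.00166). The camera call ended for the sensing genes without M1 KD replicate 5 (adjusted p = 0.0753), for adhesion genes without M1 NS replicate 2 (0.0547), for chemokine receptors without M1 NS replicate 1 (0.0534), M1 NS replicate 2 (0.0559) or M1 KD replicate 5 (0.0929), and for chemokine receptors (0.101) and the WDR5 and MLL genes (0.0746) with the trend in length, GC content and exon number removed. The medians were then -0.48 for sensing genes, -0.42 for adhesion genes, -1.17 to -0.59 for chemokine receptors and -0.33 for the WDR5 and MLL genes. With upper-quartile factors the median of the WDR5 and MLL genes shrank to -0.14.

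Other groups in M1 KD did not pass camera as a whole. Of 25 chemokine ligands 6 rose and 3 fell, the latter being Ccl3, Ccl4 and the neutrophil attractant Cxcl2 (-1.21), with a camera adjusted p of 0.549. Of 19 inflammatory cytokines 8 fell, among them Il12b (-2.13) and Il1a (-1.65), and Osm (0.86) and Il15 (0.83) rose (adjusted p = 0.0803). The platelet chemokine gene Pf4 rose by 1.74 and was the only called member of 15 erythroid and megakaryocyte markers (adjusted p = 0.0585). Adjusted over the list alone these counts were unchanged. The remaining 21 lists had camera adjusted p-values from 0.159 to 0.984.

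**Figure D3:**
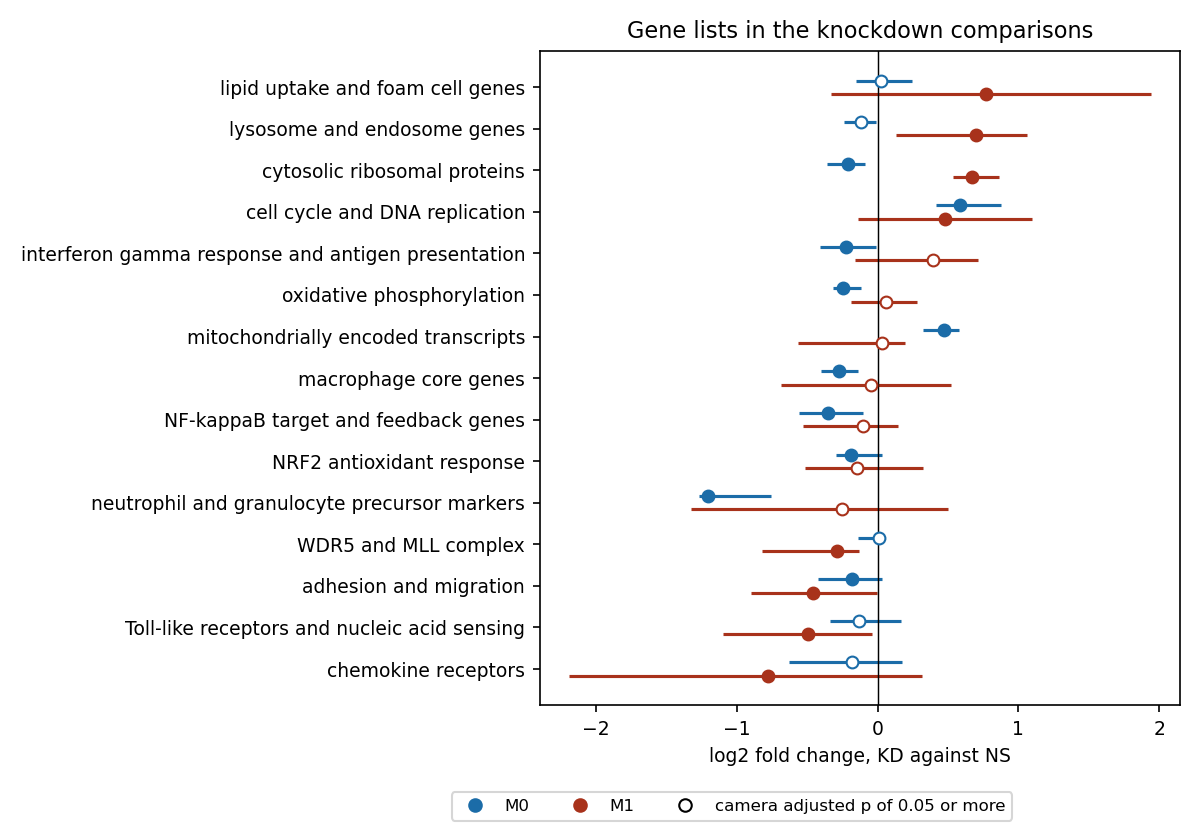
Median log2 fold change of gene lists for KD against NS in M0 and in M1, with bars from the lower to the upper quartile of the members and open circles where the camera adjusted p was 0.05 or more. Ribosomal protein genes have a median of -0.21 in M0 and 0.67 in M1, and cell cycle genes 0.58 and 0.48.

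Across all genes, edgeR called 5535 of 15024 in M1 KD against M1 NS, 2645 higher and 2890 lower, and 2767 of them had a log2 fold change of at least 1 either way. CPM ranges of the groups did not overlap for 52.4% of genes, where chance gives 20%. M1 KD carries the label numbers 5 and 6, which occur in no other group, so a batch behind these numbers cannot be told apart from the knockdown in M1. The count was 3104 with the 5 M1 libraries alone and 3658 without M1 KD replicate 5. With upper-quartile factors 3454 genes were higher and 2177 lower, so that 61.3% rather than 47.8% were higher, and the median log2 fold change of all genes was 0.15. Single-exon protein-coding genes had a median log2 fold change of -0.69 (248 genes) and those with more exons 0.03 (12224 genes).

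Whether the knockdown effect depended on the state was tested as the difference between the effect in M1 and in M0. The effect on Ccl3 was lower in M1 than in M0 by a log2 difference of -2.61 (SE 0.44, adjusted p = 0.00151), and that on Ccl4 by -3.12 (SE 0.61, adjusted p = 0.00344). Egr1 (-5.47), Fpr1 (-4.17), Rbm12 (-3.98), the exchange factor gene Psd3 (-3.61) and the Notch ligand gene Jag1 (-3.56) were taken by the rule for named genes for their negative differences. Jag1 varied widely in M1 NS, at 37.8 ± 33.6 CPM (SD, n = 3, from 18.0 to 76.7). Its difference ran from -4.23 to -2.47 over the alternatives. Frat2 (3.80), Mgll (3.48), the receptor gene Gpr160 (3.38), H2-K2 (3.38), annotated as a transcribed pseudogene, and Aph1c (3.34) were taken for their positive ones. In M1 NS, Frat2, Mgll and Gpr160 were at low levels of 0.43, 2.94 and 1.34 CPM. Ribosomal protein genes had a median difference of 0.95, with 33 of 46 called higher, 41 adjusted over the list alone, and none lower. Lysosome and endosome genes had a median difference of 0.95 as well, with 21 of 34 called higher and Stab1 lower (-1.47), and the same counts adjusted over the list alone. Camera gave adjusted p-values of 4.02e-11 and 3.76e-06 to these lists, both lost at adjusted p = 0.769 with an estimated correlation, and fry gave 0.0313 and 0.0112. Over the alternatives the ribosomal median ran from 0.62, without M1 KD replicate 5, to 1.13, and the lysosomal one from 0.52, with the trend in length, GC content and exon number removed, to 1.07. The other 30 lists did not pass camera, the cell cycle genes among them (median 0.03, adjusted p = 0.541).

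Over all genes, edgeR called 4095 differences of 15024, 1965 higher in M1 and 2130 lower. With upper-quartile factors 2474 were higher and 1705 lower, which made 59.2% rather than 48.0% higher, with a median of 0.12 over all genes. That median was -0.12 with library size as the only scaling, where 1570 were higher and 2506 lower (38.5% higher). The label numbers 5 and 6 of M1 KD bear on this comparison as on the one within M1.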

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

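Chosen only after the result was seen were the test of the granule genes, the removal of the trend in transcript length, GC content and exon number, and the splits of the 6 M0 libraries alone.

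The change from NS to KD differed between M1 and M0 for 4095 of 15024 genes, in the test of the difference itself. The label numbers of the M1 KD libraries occur in no other group. A batch behind these numbers thus cannot be told apart from a knockdown effect that depends on the state. Ccl3 (-2.61), Ccl4 (-3.12), the immediate early gene Egr1 (-5.47), the formyl peptide receptor gene Fpr1 (-4.17), Rbm12 (-3.98), Psd3 (-3.61) and Jag1 (-3.56) had lower effects in M1, as log2 differences. Frat2 (3.80), Mgll (3.48), Gpr160 (3.38), H2-K2 (3.38) and Aph1c (3.34) had higher ones. The median differences of lysosome and endosome genes and of ribosomal protein genes were 0.948 and 0.950, with both list calls lost at adjusted p = 0.769 with an estimated correlation.

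The first pattern was the breadth of the M1 response to the gapmer, 5535 genes. Removing the trend in transcript length, GC content and exon number left 5998 called genes, 4841 of them shared with the 5535, which argues against that trend as the whole cause. If every gene changes steadily from M0 to M1, a different degree of M1 activation would leave genes that do not respond to M1 alone. Yet 31.6% of 2052 such genes were called. Under that assumption this argues against it as the whole cause, but not as a part. Genes that change with M1 only for a time could be among those called, so a different timing of activation is not covered. Of the genes that rose with M1, 1113 fell in M1 KD, where independence would give 778. Of those that fell with M1, 1278 rose, where it would give 756. The shared M1 NS libraries alone give an inverse relation, but the covariance across genes was -0.33, against -0.06 in simulations with an unchanged knockdown. The simulations gave each gene the same spread in all groups and drew genes independently. They may thus understate the relation that sharing gives, since M1 NS was the most variable group. A gapmer effect common to both states is argued against too, as the whole cause of these calls. The 5535 genes had a median M0 log2 fold change of -0.0544 when signed by their direction in M1, where their median absolute change was 1.0. These genes were chosen in M1, where other causes could outweigh a common effect, so such an effect as a part is not excluded. Open are, among others, a biological effect of the knockdown particular to M1 and a different degree of M1 activation as a part. A different timing of activation and, as a part, a gapmer effect common to both states stay open as well. Open too is a culture or library batch marked by the label numbers 5 and 6. That batch cannot be told apart from the others, because M1 KD and M1 NS share 0 label numbers. Effects of the gapmer other than on its target were not tested, and the level of the target was not analysed here.

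The second pattern was the lower level of neutrophil and granulocyte precursor markers in M0 KD (median -1.21), whose call was kept with fry (0.0271) but lost at adjusted p = 0.149 with an estimated correlation. The trend in length, GC content and exon number is argued against as the whole cause, since the median was -1.12 with that trend removed. The 10 granule and lineage genes that macrophages make little of had a median of -1.18, but they are members of the same list, so this cannot part fewer granulocyte precursors among the M0 KD cells from lower expression of these genes within the macrophages. The most abundant were Ngp (460 CPM in M0 NS and 191 in M0 KD) and Ltf (370 and 156), beside S100a9 (383 and 161), and no sort or gate is given in the sources used here. Both explanations stay open, and an effect of the knockdown was not tested.

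The third pattern was the higher median of cell cycle genes in KD in both states (0.58 in M0 and 0.48 in M1), with both calls lost at adjusted p = 0.529 and 0.879 with an estimated correlation and at 0.124 and 0.153 with fry. Not every gene moved alike. With edgeR, the effect on Kif11 was lower in M1 than in M0 (log2 difference -1.68, adjusted p = 0.00505). So was that on Hmmr, which is outside the list (-2.16, adjusted p = 0.00953). Both were chosen after values were seen, and the median difference of the list was 0.03. The trend in length, GC content and exon number is argued against as the whole cause of the M0 median, which was 0.56 with it removed, and so is a single library, since the lowest M0 median without 1 of the 6 was 0.51. In M1 the median was 0.46 to 0.67 without each library, with the call lost at 0.46 without M1 NS replicate 4 (camera adjusted p = 0.125) or M1 KD replicate 6 (0.0655), so its size rested on no single library. A knockdown effect on proliferation and a difference in culture between the groups both stay open and may each account for it. For the M1 median, a different degree of M1 activation stays open too. These genes were lower with M1 itself, with a median log2 fold change of -1.73 in M1 NS against M0 NS.

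With 10 splits of 6 libraries into 3 and 3, no share under 0.05 can be reached. For M0 KD against M0 NS, the real count was 0 genes with edgeR (1947 at an unadjusted p under 0.05; 181 with DESeq2 and 0 with limma-voom and limma-trend), so that 10 of 10 splits had to give as many and nothing follows from it. The highest of the other splits gave 3. In the 6 M0 libraries alone, the real split gave 1103 genes and the highest other 16, and 1 split, the real one, gave as many. For M1 NS against M0 NS the real split gave 8338 and the highest other 0, and 1 split, the real one, gave as many.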

How the results depend on the processing

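Chosen only after the data were seen were the removal of the length, GC content and exon number trend and every repeat of the fit of the 6 M0 libraries alone. In M0 KD against M0 NS, where edgeR called 0 genes (1947 at an unadjusted p under 0.05; limma-voom and limma-trend 0), no filter on low counts gave 385, the DESeq2 Wald test 181 and the 6 M0 libraries alone 1103. In the latter fit, leaving out each library gave 0 to 1726 genes, the trend removed 18 and the replicate block 782. In M1 KD against M1 NS, 5 libraries alone gave 3104 genes, an adjusted p under 0.01 gave 3258, a log2 fold change of at least 1 gave 2767, and leaving out each library gave 3658 to 5796. The difference of effects gave 1956 at an adjusted p under 0.01 and 2552 with a log2 fold change of at least 1, and 2949 to 4751 without each library. M1 NS against M0 NS gave 4954 with a log2 fold change of at least 1, 7261 to 8633 without each library, and 8048 with the replicate block, which gave 0 genes in M0. Stricter thresholds lower counts by construction. For the other alternatives, the smaller fits included, the cause was not tested. The fit of all 11 libraries estimates 1 spread per gene over all groups. The median SD of log2 CPM was 0.18 in M0 NS and 0.14 in M0 KD, against 0.30 in M1 NS and 0.23 in M1 KD. The 0 genes called in M0 come from a fit whose spread is shared with more variable M1 groups, and do not show an absence of effect. Whether that sharing is the reason for the 0 was not tested. Without M1 KD replicate 5 or 6 the lone library was assumed to vary like the other groups. Over all groups, the numbers 1, 2 and 4 showed no clear pairing, since 3 of 9 libraries correlated best with their own number. Between M0 NS and M0 KD, same-number correlations of the deviations from the group mean were 0.135, 0.022 and 0.124. The others there ran from -0.133 to 0.032, so a pairing within M0 is not excluded.

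Ccl3 and Ccl4 kept their direction and side of the threshold in every alternative of all 4 comparisons. In M1 KD their log2 fold changes ran from -3.07 to -1.73 and from -3.95 to -2.07. Among named M1 KD genes 37 of 43 did so too, and Cxcl2, Hells, Il15, Itgb7, Tk1 and Tmem173 lost the call in at least 1 alternative. Itgb7 lost it in 7 of 16, with values from 0.06 without M1 KD replicate 5 (adjusted p = 0.891) to 2.36 without M1 KD replicate 6. In M1 NS against M0 NS 38 of 48 did. Among the others Ftl1, Msr1, Mt1, Olr1 and Spi1 lost the call in at least 1 alternative, Msr1 (0.34, adjusted p = 0.270), Spi1 (0.27, 0.216) and Olr1 (0.78, 0.0695) with library size as the only scaling. In the difference 12 of 13 did (Stab1 lost the call with the trend removed). In M0 KD only 2 of 51 did, and the other 49 passed the test with no filter, with DESeq2 or in the 6 M0 libraries alone. mt-Nd6 in M0 KD reversed to -0.0218 (adjusted p = 0.992; range over its alternatives 0.0362 to 0.992) with the trend removed, and the cause was not tested. An estimated correlation ended all list calls, 10 in M0 KD, 8 in M1 KD, 2 in the difference and 17 in M1 NS against M0 NS, and fry ended 8, 1, 0 and 0. The replicate block ended LXR targets (-1.11, adjusted p = 0.0668) and macrophage core genes (-0.88, adjusted p = 0.0668) in M1 NS against M0 NS. Depth limits genes with few counts, such as mt-Nd4l, at under 1 CPM in M0.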

Other observations

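The direction of the knockdown effect in M1 was compared with the M1 response itself, after both had been seen, and the groups by transcript length and exon number and the members of small counts named here were chosen then too. Of the genes that rose with M1, 1113 fell in M1 KD where independence would give 778, and of those that fell with M1, 1278 rose where it would give 756. Higher in both were 466 genes (712 under independence) and lower in both 541 (826). Genes with a log2 fold change of at least 1 with M1 (2198 genes) had a median of -0.18 in M1 KD, and those at or below -1 (3186 genes) one of 0.44. Both comparisons share the M1 NS libraries, which alone gives an inverse relation. In 100 simulations with an unchanged knockdown these medians were -0.04 and 0.04 on average, and the covariance across genes was -0.06 against -0.33 observed. The simulations gave each gene the same spread in all groups and drew genes independently. The median SD of log2 CPM was highest in M1 NS, at 0.30, so the relation that sharing gives may be understated. Genes are not independent replicates, and the 3 M1 NS libraries were not split between the comparisons.

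Immediate early genes went both ways in M1 KD, with 7 of 17 higher and 7 lower (8 and 7 adjusted over the list alone; fry for a change in either direction, adjusted p = 5.71e-10). Stress and unfolded protein response genes did as well, with 11 of 34 higher and 10 lower (14 and 10 adjusted over the list alone), as did alternative activation markers, with 8 of 27 higher and 6 lower (10 and 6 adjusted over the list alone). Among p53 target genes 9 of 26 were higher, and Plk3, Aen, Btg2 and Rrm2b were lower (10 and 5 adjusted over the list alone). Among 10 osteoclast markers Ctsk, Acp5, Atp6v0d2 and Itgb3 were higher and Tnfrsf11a was lower (5 and 1 adjusted over the list alone). None of these lists passed camera.

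Transcript length went with the effect in both states, in opposite directions. In M1 KD the protein-coding genes with the shortest transcripts (255 to 2189 bases, 3119 genes) had a median log2 fold change of 0.23 (819 genes higher and 350 lower) and those with the longest (4807 bases and over, 3118 genes) one of -0.25 (370 higher and 1012 lower). In M0 KD these medians were -0.13 and 0.11. Single-exon protein-coding genes (248) had a median of -0.69 in M1 KD, with 35.9% lower against 19.7% of genes with more exons, and medians of -0.07 in M0 KD and -0.06 in M1 NS against M0 NS.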
